A study of Mus musculus with 24 samples.

How the data were processed

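The values analysed were the submitters' deposited peak lists, 1 for each of 4 marks in KO and WT, with the chromosome, first base, last base and width of each peak in bp. These positions and widths, of the unit class other, are the authors' deposited values and were used without rescaling. The lists carry no score, height, fold enrichment or p per peak. According to the submitters' processing notes, Trim Galore 0.4.4, cutadapt 1.14, Bowtie2 2.2.6, SAMtools, deepTools 3.1.1 and MACS2 2.1.2.1 were used, with the genome builds mm10 for mouse and R64 for the yeast spike-in. The role of each tool, the peak threshold, the peak mode and whether the 3 samples of a group were pooled are not given in the sources used here. H3K9me3, named in the protocol, is not analysed here.

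Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. A peak was shared if it overlapped a peak of the same mark in the other genotype by at least 1 bp, and otherwise was WT-only or KO-only. Overlap at random came from 100 circular shifts of a list within each chromosome, and from 20 shifts for the location and marks of shared and genotype-only peaks. Shares carry exact Clopper-Pearson intervals at 95%, which treat peaks as independent and cover counting error only. The depth of each sample is unknown, no value per sample entered, and no test between genotypes was run.

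Genes were the 20665 protein-coding genes of GRCm38.p6 (mm10) on chromosomes 1 to 19. A gene carried a mark if a peak lay within 1000 bp of either annotated end. A gene end can lie away from the start of transcription that the cells used. Gene states combined H3K4me3 and H3K27me3. Distal regions were merged H3K4me1 peaks of both genotypes over 1000 bp from every gene end, and their active and primed states were counted where H3K4me3 was absent in both genotypes.

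The 25 gene lists, with 576 different genes of which 555 were found as protein-coding genes, were fixed with the comparisons and most alternatives before the data were examined. A list's score was the number of KO-only minus WT-only genes over members with the mark in either genotype. It was placed as a percentile among 10000 random lists drawn from genes with the mark, or 2000 under alternatives other than equal numbers. Over whole genes the score counted peaks, with 5000 bp on each side. For H3K4me3, random lists were also matched on the presence of H3K27me3 and H3K27ac at gene ends.

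Named genes followed a rule. For each mark and direction these were the 5 genes with the widest genotype-only peaks, at gene ends for H3K4me3, H3K27ac and H3K27me3 and over genes without H3K4me3 at the peak for H3K4me1. The 3 genes with the widest shared peaks of WT were added for the marks other than H3K4me1. Symbols starting with Gm or ending in Rik were passed over. A peak at the end of a named gene can belong to a neighbouring gene. Members of the gene lists whose state or H3K27ac differed between genotypes could be named, up to 8 a list in alphabetical order, as could Dnmt3a. Some genes that the rule names are not reported here.

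Some steps departed from the plan. Width replaced the planned rank by q or fold enrichment, which the lists do not carry. Either gene end replaced the transcription start, 5000 bp on both sides of a gene replaced 5000 bp upstream, and exons and introns were not separated, since the gene table has no strand or exons. Base composition of peaks was not analysed here because no genome sequence was used. Leaving out replicates and a replicate block need values per sample and were not run.

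The steps were tried on simulated lists with a known answer. Of 10000 simulated KO peaks per mark, 60% were made to overlap WT peaks, and 59.99% to 60% were recovered. This checks the overlap code only, since the simulated peaks were slightly moved WT peaks or lay away from all WT peaks. On chromosome 19, 0 of 1999 peaks differed from an exhaustive search. Of 50 simulated gene lists with a change 100% lay above the central 95% of random lists, and of 50 without a change 0% lay outside it. All members of these simulated lists had the mark, and the simulated change was large. The result therefore does not give the power or error for real lists with few marked genes or smaller changes.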

Results

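Histone marks were mapped in endothelial cells sorted by flow cytometry from the lungs of mice that lacked Dnmt3a, the gene of a de novo DNA methyltransferase, (KO) and of wild-type mice (WT). The assay, ACT-seq, loads a Tn5 transposase with an antibody, so that DNA is cut and tagged where the antibody binds. The marks were H3K4me1, found at enhancers and promoter flanks, H3K27ac, found at active enhancers and promoters, H3K4me3, found at promoters, and H3K27me3, deposited by the Polycomb system at silent genes. The labels name 24 samples, 3 for each of 8 groups of genotype and mark, and the processed data hold 1 list of peaks for each group, so that no spread between replicates, sequencing depth or peak height entered any comparison. A difference between genotypes below is therefore a difference between 2 lists, and each interval is an exact binomial interval at 95% that covers counting error only. The 8 lists held 313065 peaks on chromosomes 1 to 19 of mm10, and other chromosomes were not analysed here.

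Dnmt3a itself, at chromosome 12 from 3801559 to 3914443, carried the marks of an active gene in both genotypes. The widest H3K4me3 peak over the gene lay from 3807256 to 3808681 in WT and from 3807192 to 3808617 in KO, 1426 bp in each, and no H3K27me3 peak was listed in either genotype. The gene held 12 H3K4me1 peaks in WT and 13 in KO, of which 9 and 8 were shared, and 19 H3K27ac peaks in WT against 11 in KO. H3K4me3 gave 5 peaks in WT and 8 in KO. The 5 KO-only H3K4me3 peaks included 1 from 3833792 to 3834312 and 1 from 3855720 to 3856474, both overlapping H3K4me1 and H3K27ac peaks of both genotypes. Toward the end of the gene, 3 H3K27ac and 2 H3K4me3 peaks of WT lay beyond 3891872, the last base of any KO peak over the gene, a stretch singled out after the values were seen. Peak lists do not show which part of the gene was deleted and so do not test the genotype labels.

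**Figure D1:**
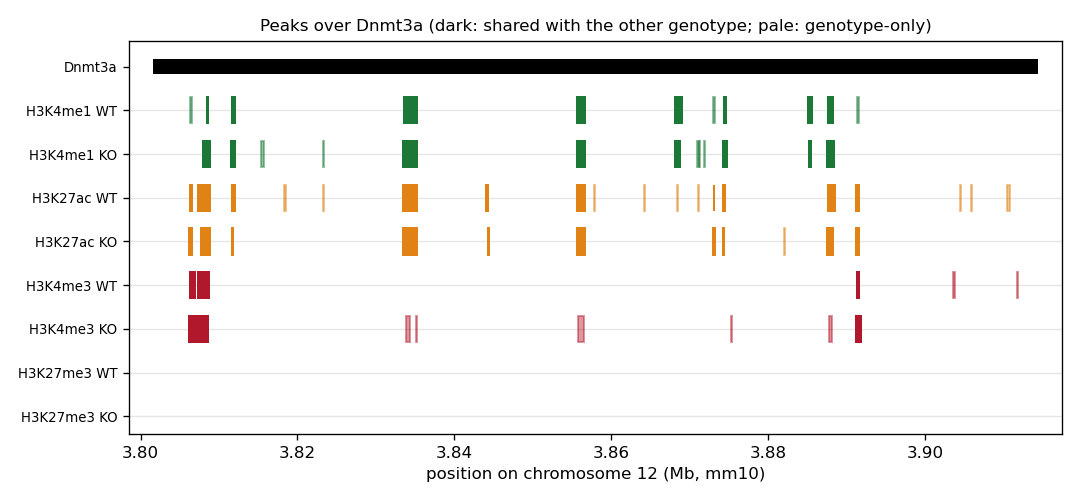
Peaks of the 8 lists over Dnmt3a, with position on chromosome 12 in Mb of mm10 on the horizontal axis and 1 line per mark and genotype; dark blocks overlap a peak of the other genotype and pale blocks do not. KO has 5 pale H3K4me3 peaks against 2 in WT, and the last KO peak ends at 3891872.

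The first comparison asked how much of the genome each mark occupied in each genotype. H3K4me3 and H3K27me3 covered more of the genome in KO, H3K27ac covered less, and H3K4me1 was spread over a similar number of wider peaks. H3K4me3 was listed at 22724 peaks (12.8 Mb) in KO and 14984 (8.79 Mb) in WT, a KO over WT ratio of 1.52 by number and 1.46 by covered length. H3K27me3 was listed at 31022 peaks (19.15 Mb) in KO and 20918 (10.1 Mb) in WT, ratios of 1.48 and 1.90. H3K27ac went the other way, with 44484 peaks (20.2 Mb) in KO and 81112 (27.6 Mb) in WT, ratios of 0.548 and 0.733. H3K4me1 had 48458 peaks in KO and 49363 (20.9 Mb) in WT, with a ratio of covered length of 1.19 and median widths of 461 and 384 bp. The excess of WT H3K27ac peaks was made of narrow peaks, since the KO over WT ratio was 0.916 among peaks of at least 500 bp (16103 in KO and 17579 in WT), while for H3K4me1 the same width limit turned the ratio from 0.982 to 1.32.

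The next comparison asked how far the 2 genotypes marked the same places. Most H3K4me1 peaks were shared, 76.5% of the WT list (interval 76.1 to 76.9) and 75.7% of the KO list (75.3 to 76.1), against 1.88% and 1.89% for randomly shifted KO peaks. Of the H3K4me3 peaks, 82.0% in WT and 51.6% in KO were shared, and of the H3K27me3 peaks 75.1% and 48.6%, so that 11004 H3K4me3 and 15947 H3K27me3 peaks were KO-only against 2704 and 5203 WT-only. H3K27ac differed the other way, with 37.0% of the WT list and 67.5% of the KO list shared and 51094 WT-only against 14470 KO-only peaks. The covered length in common, as a Jaccard index, was 0.519 for H3K4me1, 0.525 for H3K4me3, 0.416 for H3K27ac and 0.345 for H3K27me3, with shifted values of at most 0.00541. Genotype-only peaks were narrow, with a median of 164 bp for WT-only H3K27ac against 548 bp for shared ones, and of 201.5 bp for KO-only H3K4me3 against 803 bp.

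**Figure D2:**
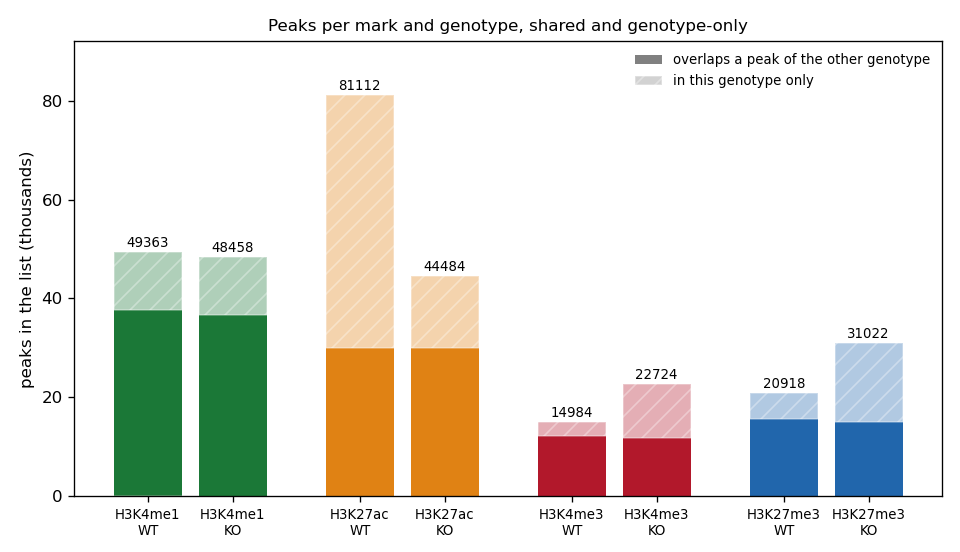
Peaks per list in units of 1000 (bar height, with the number on top) for 4 marks and 2 genotypes; solid parts overlap a peak of the other genotype by at least 1 bp and hatched parts do not. The WT H3K27ac bar is mostly hatched, with 51094 of 81112 peaks, and the KO bars of H3K4me3 and H3K27me3 are about evenly split.

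Wide peaks of the active marks were almost always found in both genotypes, whereas wide KO peaks of H3K27me3 often were not. In the widest decile of each list, 98.7% of WT H3K4me1, 98.9% of WT H3K27ac and 100% of WT H3K4me3 peaks overlapped a KO peak, and in the other direction 97.9%, 99.7% and 99.2% of KO peaks overlapped a WT peak. For H3K27me3 the widest decile of the KO list, with a median width of 1900 bp, was shared at 84.9% (83.6 to 86.2), against 97.8% (97.1 to 98.4) in WT. In the narrowest decile, only 7.35% of WT H3K27ac and 6.07% of KO H3K4me3 peaks were shared. Where a single WT peak met a single KO peak, the KO peak was wider by a median factor of 1.23 for H3K27me3 (14150 pairs), 1.18 for H3K4me3 (10606 pairs) and 1.13 for H3K4me1 (34525 pairs), and narrower for H3K27ac, with a factor of 0.953 (27829 pairs).

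**Figure D3:**
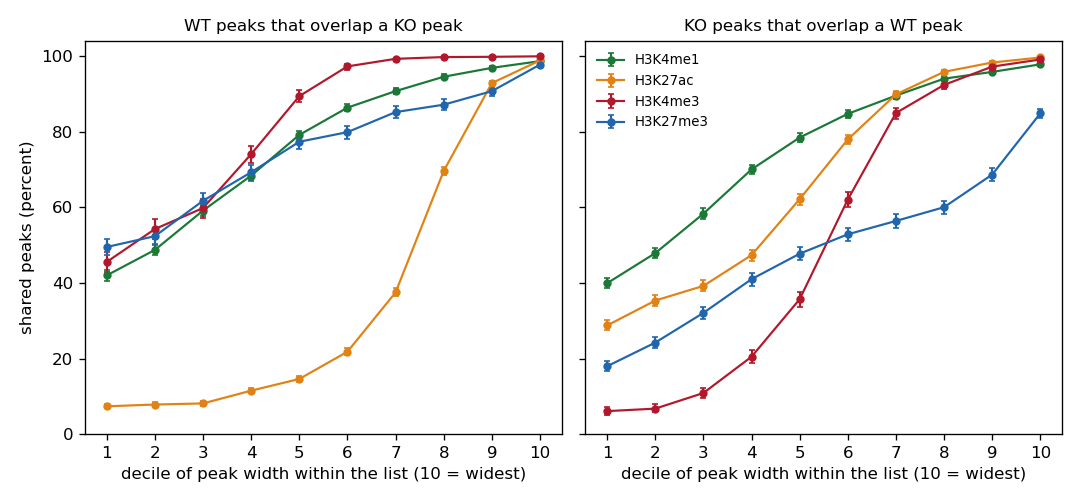
Percent of peaks that overlap a peak of the other genotype (vertical axis) by decile of peak width within each list (horizontal axis, 10 the widest), for WT lists on the left and KO lists on the right; bars are exact 95% intervals. All lines climb with width, and the KO H3K27me3 line ends lowest, at 84.9%.

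Genotype-only peaks of different marks lay in different places. WT-only H3K4me1 peaks lay within 1000 bp of an end of a protein-coding gene in 22.1% of cases (21.3 to 22.8), KO-only ones in 7.89% (7.41 to 8.40), with 3.38% and 3.55% for shifted peaks, and 60.8% of KO-only H3K4me1 peaks lay inside genes away from the ends. H3K4me3 peaks shared by both genotypes were at gene ends in 72.3% of cases, WT-only ones in 13.3% and KO-only ones in 18.8%. Between genes lay 51.2% of WT-only and 50.6% of KO-only H3K27me3 peaks, against 29.3% of shared ones. The 2 sets of genotype-only H3K27ac peaks were rarely at gene ends, 4.63% in WT and 6.13% in KO, not far above shifted peaks (3.35% and 3.40%). Because the gene table gave no strand or exons, both ends of each gene were used and inside a gene means exon or intron.

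At the ends of 20665 protein-coding genes, H3K4me3 was listed in KO only at 1426 genes and in WT only at 141, beside 9378 genes in both genotypes. The widest KO-only H3K4me3 peaks at gene ends belonged to Adamts5, an extracellular protease (chromosome 16, 85899913 to 85901604, 1692 bp), Ssh1, a cofilin phosphatase (chromosome 5, 113992989 to 113994555), Igf2r, the imprinted mannose 6-phosphate receptor (chromosome 17, 12768508 to 12770070), Phf19, a Polycomb-associated protein (chromosome 2, 34912942 to 34914385), and Plekhm2 (chromosome 4, 141663163 to 141664579). Those of Ssh1, Igf2r and Plekhm2 also had H3K27ac in both genotypes, and that of Adamts5 had H3K27me3 in both. The widest of the fewer WT-only H3K4me3 peaks at gene ends lay at Cacng8 (969 bp), Arrb1 (960 bp), Gpr3 (835 bp), Arl4d (825 bp) and Cdc42ep1 (770 bp). Arrb1, Arl4d and Cdc42ep1 had another H3K4me3 peak at an end in KO. The widest shared H3K4me3 peaks of WT lay at Tsc22d2 (3263 bp), Cdk6 (2823 bp) and Ptprm (2688 bp), all with H3K4me1 and H3K27ac in both genotypes. With equal numbers of the widest peaks from each list, the ratio of KO-only to WT-only genes was 2.77 in place of 10.1.

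H3K4me1 at gene ends differed in the opposite direction, with 1968 genes in WT only, 486 in KO only and 7658 in both. Of the 1968 genes, 73.7% had H3K4me3 at an end in WT and 85.3% in KO, and 78.2% had H3K27ac in WT and 73.4% in KO. Of the 7658 genes with H3K4me1 in both genotypes, 92.9% had H3K4me3 and 92.6% H3K27ac in KO. Away from H3K4me3, the widest WT-only H3K4me1 peaks over genes were in Jazf1 (chromosome 6, 52775313 to 52776326, 1014 bp, with H3K27ac in both genotypes), Cspp1 (900 bp), Ranbp9 (854 bp), Sik2 (819 bp) and Avl9 (813 bp). The widest KO-only ones were wider and lay in Tcf4, a basic helix-loop-helix factor (chromosome 18, 69383000 to 69384718, 1719 bp, with H3K27ac in both genotypes), Kank2 (chromosome 9, 21768431 to 21770090, 1660 bp, with H3K27ac in KO), Fam102a (1445 bp), Ksr1 (1408 bp, with H3K27ac in KO) and Prkce (1374 bp).

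H3K27ac at gene ends was listed in WT only at 1216 genes, in KO only at 416 and in both at 9435. The widest WT-only H3K27ac peaks lay at Snrpb (1341 bp), Traf4 (1252 bp), Cyp4a32 (1141 bp), Adamdec1 (1098 bp) and Mb21d2 (1091 bp), and of these Mb21d2 had another H3K27ac peak at an end in KO. The widest KO-only H3K27ac peaks lay at Pam (1163 bp), Cpd (1100 bp), Tmem38b (849 bp), Syncrip (823 bp) and Cst3 (804 bp), and of these Tmem38b had no H3K27ac at an end in WT. The widest shared H3K27ac peaks of WT lay at LOC108167694 (3106 bp), Cnksr3 (2461 bp) and Sh3glb1 (2425 bp). The KO-only over WT-only ratio of 0.342 was 0.490 with peaks under 200 bp left out of both lists, and 1.01 with equal numbers of the widest peaks, which shortens the WT list alone.

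H3K27me3 at gene ends was listed in KO only at 1712 genes, in WT only at 708 and in both at 7119. The widest KO-only peaks were several kb long and carried no other mark in either genotype. They lay at Ap5b1 (chromosome 19, 5557724 to 5562109, 4386 bp), Camkv (chromosome 9, 107935237 to 107939018, 3782 bp), Th, the gene of tyrosine hydroxylase (chromosome 7, 142898938 to 142902515, 3578 bp), Sema4d (chromosome 13, 51790855 to 51794216, 3362 bp) and Plcxd1 (chromosome 5, 110099130 to 110102353, 3224 bp), and none of these genes had H3K27me3 at an end in WT. The widest WT-only peaks were at Stau2 (1573 bp), Kcp (1409 bp), Rnf152 (1331 bp), Nalcn (1252 bp) and Hacd1 (1167 bp), and Stau2, Rnf152 and Hacd1 also had H3K27ac and H3K4me3 in both genotypes at the peak. Shared H3K27me3 peaks were widest at Col9a2 (3305 bp), Stac (3217 bp) and Mnat1 (3167 bp). The peaks of Ap5b1, Th and Mnat1 were centred outside the gene and may belong to a neighbour. With equal numbers of the widest peaks, which shortens the KO list alone, the KO-only over WT-only ratio of 2.42 became 0.666.

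Each gene was then given a state by H3K4me3 and H3K27me3 at its ends. In WT, 4222 genes had H3K4me3 alone, 5297 both marks, 2530 H3K27me3 alone and 8616 neither, and in KO 4352, 6452, 2379 and 7482. From H3K27me3 alone in WT, 618 genes had both marks in KO, and 52 genes went the reverse way, which became 384 and 110 with equal numbers of the widest peaks. From H3K4me3 alone in WT, 973 genes had both marks in KO, and 513 went the reverse way, a direction that turned with equal numbers of the widest peaks (533 and 1249). Most genes with both marks also had H3K27ac, 95.5% of them in WT (94.9 to 96.1) and 86.6% in KO (85.8 to 87.4). Genes with H3K4me3 alone had H3K27ac at 93.1% in WT and 86.6% in KO. Of 26 housekeeping genes, 14 had H3K27me3 at an end in either genotype. Whether H3K27me3 calls at genes with H3K27ac, here and in the gene lists, are Polycomb marking or open-chromatin background was not tested. Among the 2030 genes with H3K27me3 in both genotypes and H3K27ac in neither, H3K4me3 was listed at 9.46% in WT and 23.0% in KO, with 313 KO-only and 38 WT-only genes, while H3K4me1 was listed at 20.2% in WT and 11.4% in KO. The direction was not particular to them. At 9435 genes with H3K27ac in both genotypes, H3K4me3 was in KO only at 546 and in WT only at 22, and H3K4me1 was at 88.4% in WT and 76.3% in KO. At 6822 genes with neither H3K27me3 nor H3K27ac, H3K4me3 was in KO only at 185 and in WT only at 38.

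Because the series is titled for the enhancer landscape, H3K4me1 regions over 1000 bp from every gene end were compared. Only the outer ends of protein-coding genes were used, so that these regions can include promoters inside genes or of noncoding genes. Of 49071 such distal regions, 4943 (10.1%) had H3K4me3 in KO only, 425 (0.866%) in WT only, 2837 in both and 40866 in neither. Of the 4943 regions, 84.9% had H3K27ac in WT and 84.3% in KO, 87.1% had H3K4me1 in both genotypes and 57.3% overlapped a protein-coding gene, against 42.9%, 39.5%, 54.6% and 60.7% of the regions without H3K4me3. Among the 40866 regions without H3K4me3, 11113 were active (H3K4me1 with H3K27ac) in both genotypes, 5763 were primed (H3K4me1 without H3K27ac) in both, 2944 were active in WT and primed in KO, and 2485 the reverse. A further 10409 had no H3K4me1 in WT, of which 9082 were primed in KO, and 8152 had none in KO, of which 6460 were primed in WT. H3K27me3 was found at 3.41% of primed regions in WT (3.12 to 3.71) and 4.37% in KO (4.07 to 4.68), and at 5.76% and 5.83% of active ones. With equal numbers of the widest peaks the ratio of KO-only to WT-only H3K4me3 at distal regions was 3.34 in place of 11.6, and the regions that went from active to primed and the reverse numbered 1883 and 4116. That setting shortens the longer list of each mark, which was that of WT for H3K27ac and that of KO for H3K4me3.

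Marks also combined differently in the 2 genotypes. KO-only H3K4me3 peaks overlapped WT H3K4me1 in 51.5% of cases (50.5 to 52.4) and WT H3K27ac in 50.0%. With the WT lists of those 2 marks shifted, the shares were 1.42% and 2.00%. WT-only H3K4me3 peaks overlapped WT H3K4me1 in 17.4% of cases. Of KO-only H3K4me1 peaks, 20.1% overlapped WT H3K27ac and 16.0% KO H3K27ac, and of WT-only ones 35.3% and 29.9%. WT-only H3K27ac peaks overlapped WT H3K4me1 in 10.5% of cases, against 86.3% for shared H3K27ac peaks. H3K27me3 peaks lay on H3K27ac of the same genotype in 41.4% of cases in WT and 27.9% in KO, against 2.68% and 1.92% for shifted H3K27ac peaks. The counts were alike, 8664 of 20918 peaks in WT and 8643 of 31022 in KO, so that the lower KO share went with the longer KO list. Away from H3K27ac of either genotype, H3K27me3 had 21022 peaks (13.7 Mb) in KO and 11953 (6.06 Mb) in WT, ratios of 1.76 and 2.25, while on H3K27ac it had 10000 and 8965, and only 36.3% of the 21022 KO peaks were shared.

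Lists of genes fixed beforehand were compared at gene ends, as KO-only minus WT-only genes among members with a peak, and placed among 10000 random lists of as many marked genes. Of 100 pairs of list and mark, 11 lay outside the central 95% of random lists, where about 5 would do so at random. That number is a rough guide, since lists share genes, neighbouring genes can share peaks, and scores of few marked genes take few values. By mark the 11 were 1 for H3K4me1, 3 for H3K27ac, 5 for H3K4me3 and 2 for H3K27me3. With equal numbers of the widest peaks they were 1, 2, 2 and 1, which is close to the number at random. In the endothelial lists most genes with H3K4me3 or H3K27ac at an end had it in both genotypes. Of 25 pan-endothelial genes, 19 had H3K4me3 in both genotypes and 1, Erg, in KO only. H3K27ac was in both at 21, with Fli1 and Icam2 in WT only and Ets1 in KO only. Fli1, Icam2 and Ets1 had no H3K4me3 at an end in either genotype. Erg had H3K27me3 in both genotypes and H3K27ac in neither. At these genes the annotated ends may lie away from the start of transcription that the cells used, so a promoter change is not shown. H3K27me3 was in KO only at Cdh5 and Esam and in WT only at Robo4, each with H3K4me3 and H3K27ac in both genotypes. Among general capillary genes, 12 of 13 had H3K4me3 in both genotypes, with Tmem100 in KO only, and H3K27ac was listed at Cxcl12 in WT only, while H3K27me3 was in both at 2 of 7, in WT only at 3 and in KO only at 2. Among aerocyte genes, 10 of 11 had H3K4me3 in both, with Fibin in KO only, H3K27ac was in WT only at Prx and in KO only at Car4, and H3K4me1 was in both at 5 of 10 and in WT only at 4. The arterial list held 16 of 17 genes with H3K4me3 in both genotypes and 1, Gja5, in WT only (percentile 1.48, range 1.55 to 8.52 over 6 other settings), and H3K27ac was in WT only at Dkk2 and Jag2. In the venous list H3K27ac was in WT only at 3 of 8 genes, Car8, Nr2f2 and Slc6a2 (percentile 2.44, range 0.825 to 24.5), and in the lymphatic list H3K4me3 was in WT only at Lyve1 and in KO only at Reln.

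Genes of developmental transcription factors of other lineages were among the lists with the highest H3K4me3 scores, below the lung mesenchyme and epithelium lists (83.3% and 66.7%). Of the 74 in the table, 68 had H3K27me3 in both genotypes and 3 in KO only, and H3K4me3 was listed at 8 in both, at 15 in KO only and at none in WT only (percentile 100, range 99.0 to 100 over 6 other settings). The KO-only genes included Dlx6, En2, Irx2 and Isl1, all with H3K27me3 in both genotypes and no H3K27ac in either. Hand1 and Hand2 had H3K27me3 in KO only and no H3K4me3. At the same 74 genes H3K4me1 was in WT only at 13 and in KO only at 4, and H3K27ac in WT only at 4, with Irx3 among them, and in KO only at 2. The last 2 are neighbours with overlapping ends. Random lists matched on H3K27me3 and H3K27ac had a median KO-only excess of 39.1% against 65.2% for this list, which lay at percentile 99.3 among them. Hox genes had H3K27me3 in both genotypes at 29 of 39 and in KO only at 6, and H3K4me3 in both at 6, in KO only at 4, Hoxa13, Hoxa3 and Hoxc5 among them, and in WT only at 2, Hoxb5 among them (percentile 69.1). Among matched lists the Hox genes lay at percentile 13.1, with a KO-only excess of H3K4me3 of 16.7% against a median of 33.3%. Their H3K4me1 was in KO only at 4 and in WT only at 2 (percentile 99.0, range 92.9 to 99.3).

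Imprinted genes, expressed from the chromosome of a single parent, leaned to WT in H3K27ac. Of 15 with H3K27ac at an end, 8 had it in both genotypes, 7 in WT only and none in KO only (percentile 0.035, range 0 to 1.58 over 6 other settings). Among the 7, Peg10 and an adjacent member had the same calls for all marks at neighbouring ends, so that 1 place counted as 2 genes. The 7 included Igf2, a fetal growth factor, Ndn, Nnat, Peg10 and Rtl1. In WT, Igf2, Ndn and Nnat had H3K27me3 alone and Rtl1 neither H3K4me3 nor H3K27me3, while others of the 7 had H3K4me3. Over all genes in either of those states, H3K27ac was also listed at a larger share in WT than in KO. Random lists for H3K27ac were not matched on other marks. Whether the lean to WT is particular to imprinted genes was therefore not tested. H3K4me3 was in KO only at 5 imprinted genes, Igf2, Igf2r, Ndn and Phlda2 among them, and in WT only at none (percentile 98.0, range 85.5 to 99.1). Of these, Igf2, Ndn and Phlda2 had H3K27me3 in both genotypes, so that Igf2 and Ndn had H3K27ac without H3K4me3 in WT and H3K4me3 without H3K27ac in KO. Peg10 had H3K4me3 in both genotypes with H3K27me3 in KO only, and Gnas had H3K27me3 in KO only. Over the list H3K27me3 was in KO only at 3 genes, Peg10 and its adjacent member among them, and in WT only at 2, Nnat among them (percentile 38.8).

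**Figure D4:**
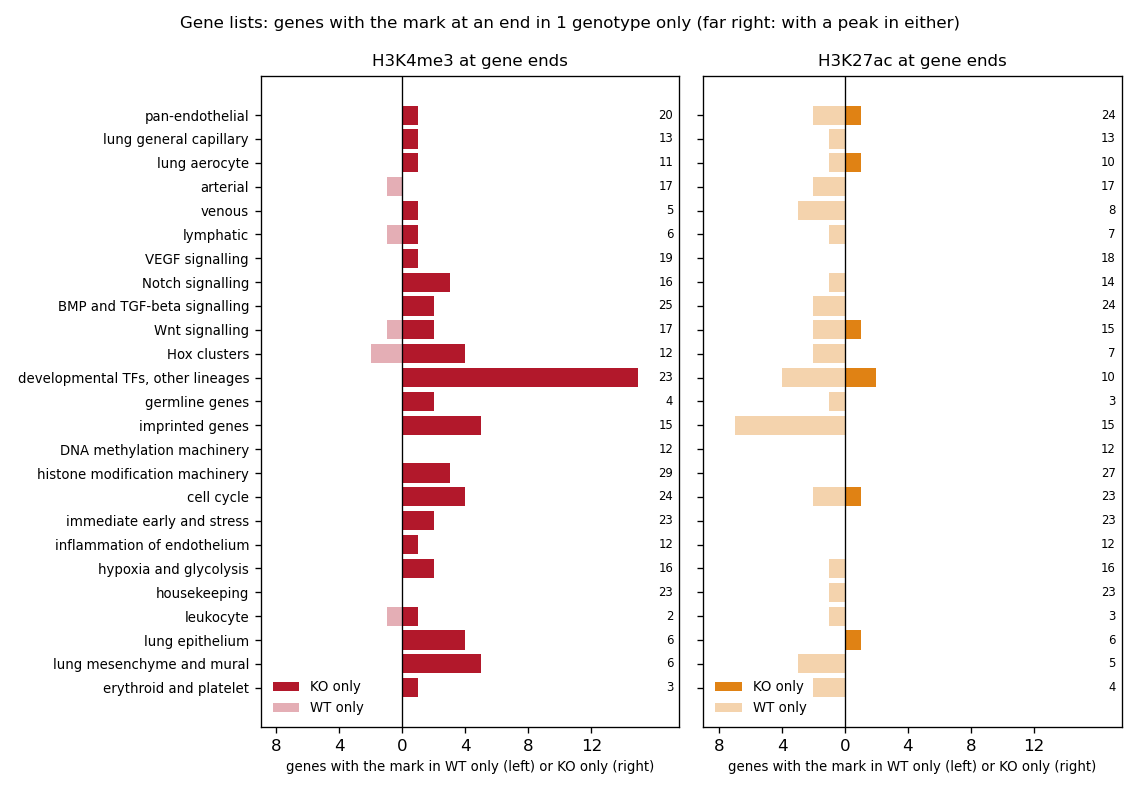
Genes with H3K4me3 (left) or H3K27ac (right) at an end in WT only (pale, to the left) or KO only (dark, to the right) for 25 gene lists, with the number of members that have the mark in either genotype at the far right. The developmental transcription factors reach 15 KO-only genes for H3K4me3, and the imprinted genes 7 WT-only genes for H3K27ac.

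Genes of cell types other than endothelium, which a lung endothelial sort could carry over, were mostly unmarked by H3K27ac. Of 28 leukocyte genes, 2 had H3K27ac at an end in both genotypes and 1, Coro1a, in WT only. The lung epithelium list had H3K27ac at 5 of 21 genes in both genotypes and at 1, Foxj1, in KO only, and its H3K4me3 was in KO only at 4, Elf3, Epcam, Foxj1 and Scgb1a1 (percentile 99.9, range 87.6 to 99.9). The mesenchyme and mural list had H3K4me3 in KO only at 5 of 21 genes, Acta2, Col1a2, Kcnj8, Myh11 and Rgs5 (percentile 99.98, range 91.8 to 100), while H3K27ac was in WT only at 3, Col1a2, Rgs5 and Tcf21 (percentile 0.560, range 0.1 to 10.6). Among 13 erythroid and platelet genes, H3K27ac was in both genotypes at 2 and in WT only at 2, Epor and Pf4. Among lists matched on H3K27me3 and H3K27ac the H3K4me3 percentiles were 99.3 for epithelium and 99.97 for mesenchyme. Among unmatched lists they lay inside the central 95% when equal numbers of the widest peaks were used (87.6 and 91.8).

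In signalling and housekeeping lists, H3K4me3 was in both genotypes at 18 of 19 VEGF genes (Src in KO only), 13 of 16 Notch genes (Heyl and Mfng among 3 in KO only), 23 of 25 BMP and TGF-beta genes, 14 of 17 Wnt genes (Sfrp1 and Wnt5a in KO only, Lef1 in WT only), 20 of 24 cell cycle genes, 26 of 29 histone-modifying genes and 23 of 23 housekeeping genes. H3K27me3 was in KO only at 6 BMP and TGF-beta genes, 4 Notch genes and 4 housekeeping genes and in WT only at 1, 1 and 0, inside the central 95% for each list. Inflammatory genes had H3K27me3 in KO only at 6, Cxcl10, Icam1, Il6, Irf1, Irf7 and Nfkb1, and in both at 7 (percentile 99.3, range 73.6 to 99.3). Of these, Icam1, Irf1, Irf7 and Nfkb1 had H3K27ac in both genotypes, and Cxcl10 and Il6 in neither. DNA methylation genes had H3K27me3 in KO only at 5, Dnmt3l, Mbd4, Tet3, Uhrf1 and Zbtb4, and in both at 6 (percentile 98.7, range 79.1 to 98.7). All of the named genes but Dnmt3l had H3K27ac in both genotypes. Germline genes, several of which are silenced by DNA methylation, were marked at few ends, with H3K4me3 in KO only at Dazl and Spo11 and in both genotypes at 2. Immediate early genes had H3K4me3 in both genotypes at 21 of 23 and hypoxia genes at 14 of 16.

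Over whole genes with 5000 bp on each side, H3K27ac peaks of leukocyte genes were WT-only in 16 cases, KO-only in 1 and shared in 5, where random lists had a median excess of WT-only peaks too (score -68.2% against -31.2%, percentile 0.020). The H3K27ac score, KO-only minus WT-only peaks over all peaks, was also low for erythroid and platelet genes (-63.6%, percentile 0.660), mesenchyme and mural genes (-54.8%, 1.28), imprinted genes (-49.4%, 1.44) and Hox genes (-54.8%, 1.94). It was high for inflammatory genes (-11.9%, percentile 98.6), hypoxia genes (-12.1%, 98.7) and, at the border of the central 95%, immediate early genes (-15.8%). H3K4me1 over germline genes was in 6 WT-only, no KO-only and 7 shared peaks (percentile 0.135). Of 50 such pairs of list and mark, 9 lay outside the central 95%, where about 2.5 would do so at random, as rough a guide as above. Gene bodies were not compared under other settings.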

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

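Some settings were chosen only after the data had been seen: peaks of at least 200 bp, the gene end that bears H3K4me3, the 500 bp window for gene lists, and 10000 in place of 2000 random lists under equal numbers. No paired analysis was possible because each genotype and mark has 1 list. The stricter thresholds by q or fold enrichment, leave-one-out, the replicate block and the base composition of peaks were not run. Autosomes alone changed nothing, since the lists hold chromosomes 1 to 19 only. Of the main values under alternatives, 95 kept their direction and stayed within a tolerance, 58 moved beyond it and 4 ratios crossed 1. The tolerance was 1.5 times the reported value for ratios and counts, and the 95% interval of the reported value for percents and percentage points, which is far narrower. For the percentiles of single lists, 40 stayed outside the central 95% of random lists and 26 did not. Unless said, the cause was not tested. Depth per sample is unknown, and its effect on list length was not measured.

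Equal numbers of the widest peaks removed the narrow peaks of the longer list by construction. The shared percent of both lists was then 60.3 for H3K27ac, 75.8 for H3K4me3 and 61.3 for H3K27me3. KO-only minus WT-only percentage points at gene ends were 1.06, 9.07 and -7.82. H3K27me3 peaks lay on H3K27ac in 38.9% of cases in WT and 30.2% in KO, and KO-only H3K4me3 on WT H3K4me1 in 68.4%. The KO-only over WT-only ratio of genes was 2.77 for H3K4me3, reversed to 0.666 for H3K27me3, and was 1.01 for H3K27ac, where the difference was gone rather than turned. Genes from H3K27me3 alone in WT to both marks in KO numbered 384, and the reverse 110. At distal regions the KO-only over WT-only ratio of H3K4me3 was 3.34, and 1883 regions went from active to primed and 4116 the reverse. Lists outside the central 95% numbered 2 for H3K4me3 and 1 for H3K27me3.

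With peaks within 1000 bp merged, the shared percent was 79.2 for H3K4me1, 49.0 for H3K27ac, 64.8 for H3K4me3 and 60.6 for H3K27me3, H3K27ac at gene ends differed by 0.910 points, H3K27me3 lay on H3K27ac in 43.9% (WT) and 30.4% (KO) of cases, and KO-only H3K4me3 on WT H3K4me1 in 54.7%.

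With peaks of at least 200 bp, the shared percent in the same order was 76.8, 62.8, 72.8 and 59.9, and the points at gene ends were -18.3, 0.631, 9.78 and -4.75. KO-only H3K4me3 lay on WT H3K4me1 in 60.6% of cases, the KO over WT number of H3K4me1 peaks reversed to 1.06, and lists outside numbered 0 for H3K4me1 and 1 for H3K27me3. With peaks of at least 500 bp that number reversed to 1.32 for H3K4me1 and moved to 0.916 for H3K27ac.

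Stricter or looser sharing changed the shared percent, in the same order, to 67.8, 42.1, 57.3 and 49.2 when 50% of the peak had to overlap, to 57.8, 36.2, 47.7 and 38.0 when 50% of both peaks had to, and to 80.1, 52.3, 66.7 and 60.7 when peaks within 500 bp counted.

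With a 2500 bp window at gene ends, the points were -13.3 for H3K4me1 and 1.98 for H3K27ac, and lists outside numbered 0 for H3K4me1 and 1 for H3K27me3. With a 500 bp window, lists outside numbered 3 for H3K4me1, 5 for H3K27ac and 4 for H3K27me3. With the gene end that bears H3K4me3, the KO-only over WT-only ratio for H3K4me1 was 0.162, and no list lay outside for H3K4me1 (0).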

Other observations

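Tests with peaks of at least 200 bp, with matched random lists, with genes of other cell types and of WT-only H3K27ac on H3K4me1 were chosen only after the result was seen, as were the shared-peak and KO-only shares set beside the overlap with H3K4me3.

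H3K4me1 at gene ends was listed in WT only at 1968 genes and in KO only at 486. A longer WT list is argued against as the source. With peaks of at least 200 bp the KO list is the longer (1.06 times the WT number), and the WT-only over KO-only ratio was 3.19, against 4.05 with all peaks. A difference in peak calling at gene ends stays open. WT-only peaks there had a median width of 260 bp, against 489 bp for shared WT peaks, so that most of them pass the 200 bp limit. The ratio was not computed at a wider limit. A planned test with equal numbers was set aside because it drops few peaks of these lists. Open-chromatin background in the WT library could add such peaks: 78.1% of WT-only H3K4me1 peaks at gene ends overlapped H3K4me3, above the bound of 50% set beforehand for this cause and above the 43.0% of KO-only peaks. It stays open because 87.1% of shared peaks overlapped H3K4me3 too, so that the overlap does not tell background from signal. Widening of H3K4me3 at the same genes also stays open, with a KO over WT width ratio 1.06 times that at genes with H3K4me1 in both genotypes, and so does an effect of Dnmt3a loss, which 1 list per genotype cannot separate from a difference between libraries.

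H3K4me3 was listed in KO only at 15 developmental transcription factor genes and in WT only at 0. With equal numbers of the widest peaks the list still lay at percentile 99.0 among 10000 random lists (a first run with fewer random lists was also outside the central 95%). That does not settle whether the longer KO list is the cause. Equal numbers do not equalise width, and the KO peaks still covered more of the genome. Only 2 lists lay outside the central 95% for H3K4me3 under equal numbers, this list among them, which is close to the number at random. A difference between the H3K4me3 libraries therefore stays open. The general change of genes with H3K27me3 and no H3K27ac accounts for part, since matched random lists had a median of 39.1% against 13.0% for unmatched ones, yet the list, at 65.2%, lay at percentile 99.3 among them. The matched Hox list lay at percentile 13.1, and matching was not combined with equal numbers. The matched test replaced an earlier one, on background in all KO libraries, which compared the H3K4me1 of the developmental transcription factor list (13 WT-only and 4 KO-only genes) and its H3K27ac (4 and 2). The earlier test was set aside because both marks lean to WT-only over all genes. Cells of other types in the KO sort could bring such peaks: H3K4me3 was in KO only at 4 epithelial, 5 mesenchymal and 1 leukocyte genes and in WT only at 0, 0 and 1 (matched percentiles 99.3, 99.97 and 18.3), though with equal numbers of the widest peaks the epithelial and mesenchymal lists lay at 87.6 and 91.8. Under that setting mesenchymal H3K27ac leaned to WT (percentile 0.925), and H3K27ac at 70 leukocyte, epithelial and mesenchymal genes, with 1 KO-only and 2 WT-only genes (-1), was too little to decide, by a bound rewritten after the value was seen, so that this and an effect of Dnmt3a loss stay open.

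The WT H3K27ac list held 81112 peaks and the KO list 44484. Narrow peaks made up most of the difference, since among peaks of at least 500 bp the KO over WT ratio was 0.916. Whether these narrow peaks lay near the calling threshold cannot be told, because the lists carry no score or height. Loss of H3K27ac at distal H3K4me1 regions in KO is argued against as the main source of the longer list, since only 10.5% of WT-only H3K27ac peaks overlapped WT H3K4me1. Whether such regions lost H3K27ac on balance stays open: 2944 went from active in WT to primed in KO and 2485 the reverse, and a planned test with equal numbers was set aside because it shortens the WT list alone. Depth and spike-in scaling per sample were not used here and stay open as sources of the narrow peaks.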
